A study of Canis lupus familiaris and Gorilla gorilla and Rattus norvegicus with 12 samples.

How the data were processed

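Methylation was measured by whole-genome bisulfite sequencing of genomic DNA from mature sperm, in which unmethylated cytosines are read as thymine and methylated ones as cytosine. Per the labels, the samples were 12 libraries from 7 animals: 1 gorilla (2 libraries), 2 rats (1 library each) and 4 dogs (2 libraries each). The labels name paired-end Illumina adaptors and standard genomic libraries. The deposited values list CpG sites with both strands merged, and the libraries of the gorilla and of each dog had been pooled by the authors. For each site the authors gave the methylation level as a fraction, the share of reads that were methylated, and the deposited read count over the site. In the gorilla values the count stood beside the site's CpG label. The level multiplied by the read count gave a whole number, within 0.01 reads or 1e-05 of the read count where that is larger, at 100% of covered sites, so methylated and unmethylated reads were taken from these columns. Uncovered sites were listed at a level of 0 and were left out. Aligner, trimming and counting tools are not given in the sources used here. The labels name the builds rn5 and canFam3, and the gorilla build is not given in the sources used here. Rat sites marked CpGx by the authors, 2.09% in R1 and 2.07% in R2, were kept, and an alternative left them out. The meaning of the mark is not given in the sources used here.

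Values of a pooled animal counted as 1 replicate. Comparisons, tests, thresholds and alternatives were chosen before the data were examined, and alternatives added later are named as such. Levels were means over autosomal CpGs with at least 5 reads, low levels were under 0.2 and high levels over 0.8. Depth was the mean or median number of reads over listed CpGs. Rats were compared with dogs by a two-sided exact permutation test on animal values, with all 15 splits enumerated and Benjamini-Hochberg adjustment over 9 measures. The gorilla was given as a value with no test. Wilson intervals at 95% were given for shares in single animals.

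Hypomethylated regions were called in each animal by a hidden Markov model with a hypomethylated and a methylated state. Its beta-binomial emissions were trained on chromosome 1 in 12 rounds, with at most 50 reads counted per CpG. A region was a run of CpGs with a posterior over 0.5 and at least 5 covered CpGs, split at gaps over 1000 bp between covered CpGs. Regions were described on autosomes by number, median length, covered length and share of the autosomal span. Overlap within a species was the share of regions with any overlap in the other animal, averaged over both directions, and the Jaccard index in bp. CpG-dense clusters were merged 500-bp windows with at least 25 listed CpGs, an annotation-free stand-in for CpG islands, and counted as hypomethylated under a mean level of 0.2. Local density was the number of other CpGs within 250 bp on either side. X was compared with the autosomes as a difference of mean levels.

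For the rats, reads were summed over each region of the union of both animals' regions with at least 5 covered CpGs in both, and compared by a two-sided Fisher exact test. For the dogs, Doberman against other dogs was tested per region of the 4 dogs' union with edgeR 4.0.16, on methylated and unmethylated read counts. The model had animal effects and a methylation by breed group term and used a common dispersion and the quasi-likelihood F test. Calls in both comparisons needed a Benjamini-Hochberg adjusted p under 0.05 and a level difference of at least 0.2. The rats were also compared in 1-kb tiles. Alternatives for the dogs were limma 3.58.1 on logit levels with a prior count of 0.5, 1-kb tiles, the other splits of the dogs and leaving out each dog. A limma test with trend on arcsine square root levels was chosen after seeing the data. Other work used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0, pandas 2.3.3, PyArrow 21.0.0 and matplotlib 3.10.9.

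Named regions followed a rule. Between animals these were the 10 regions with the largest absolute difference among those past the threshold. For each species, hypomethylated regions on numbered chromosomes or X were merged over its animals. The 5 longest that overlapped a region in every animal were named. Since the edgeR test called 0 regions, the dog regions named were taken by the same rule from the arcsine test and were thus chosen after their values were seen. Coordinates count from 1. Genes were not named, and the planned comparison of promoter methylation in gene lists was left out, because the annotation used here describes a dog assembly other than canFam3 and holds no positions on rn5 or the gorilla build. The mitochondrial genome and unplaced gorilla sequences were kept out of the comparisons.

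The methods were tested on simulated data. On simulated chromosomes drawn from each animal's fitted model, 98.0 to 98.9% of simulated regions were found and 1.51 to 3.66% of called regions were false. The simulated regions were those the same model had called, with levels drawn from its own fit. High recovery was thus nearly fixed in advance and gives no rate of false calls among the real regions. In simulated rats 200 regions were changed at each size. The test recovered 38.5% of changes of 0.2, 79% of 0.3 and 99.5% of 0.5, with 5 false calls among 87926 regions. These reads were drawn with no spread beyond binomial counting. The few false calls therefore say nothing of false calls in the real rats. In simulated dogs edgeR recovered 5% of changes of 0.3, 29.5% of 0.5 and 67% of 0.7 with 0 false calls, at a common dispersion of 0.140, below the 0.178 of the real regions. The limma test on logit levels recovered 0 of 200 at each of these shifts. The arcsine test recovered 59.5%, 99.5% and 100%, with 22 false calls among 104321 regions. Alternatives tried were other coverage minimums, reads thinned at random to a mean of 7.33 per CpG, other limits for levels, regions and clusters, runs of CpGs whose centred 11-CpG mean was under 0.4, and leaving out each animal.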

Results

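Cytosine methylation was measured by whole-genome bisulfite sequencing in mature sperm of 7 animals from 3 mammalian species. The animals were 1 gorilla, 2 rats (R1 and R2) and 4 dogs. The dogs were a pair of Dobermans (DOB0024 and DOB0027), 1 Labrador (LAB0026) and 1 Portuguese water dog (PWD0093). The gorilla and each dog were sequenced as 2 libraries and each rat as 1 library, giving 12 libraries, and the values of an animal's libraries had been pooled. The unit of replication was therefore the animal, and the gorilla values have no replicates. The gorilla values covered 28451114 listed CpG sites, the rat values 24713205 and the dog values 25152651. Mean coverage of autosomal CpGs was 11.2 reads in the gorilla, 7.88 in rat R1 and 7.33 in rat R2. It was 23.8 reads in DOB0024, 14.6 in DOB0027, 18.8 in LAB0026 and 28.2 in PWD0093. At least 5 reads covered 79.9% of autosomal CpGs in the gorilla, 70.6 to 74.7% in the rats and 82.7 to 93.9% in the dogs. Intervals given for single animals cover counting error only. They take CpGs or clusters as independent, although neighbouring CpGs are not, so they are too narrow. Reads of an amplified library are not independent molecules either.

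The first comparison asked how methylated the sperm genome was in each species. Most autosomal CpGs were highly methylated in sperm of all 3 species, beside a smaller fraction of nearly unmethylated CpGs. The mean methylation level was 0.716 in the gorilla, 0.772 ± 0.0156 (SD, n = 2) in rats and 0.761 ± 0.0108 (SD, n = 4) in dogs. Partly methylated CpGs were a smaller share in every dog than in either rat. CpGs at levels from 0.2 to 0.8 made up 14.0% ± 2.31 (SD, n = 4) in dogs and 22.0% ± 1.82 (SD, n = 2) in rats, and 32.04% in the gorilla. Highly methylated CpGs, over 0.8, made up 72.3% ± 1.39 (SD, n = 4) in dogs, 66.5% ± 2.63 (SD, n = 2) in rats and 55.2% in the gorilla. CpGs under 0.2 made up 13.7% ± 1.29 (SD, n = 4) in dogs, 11.5% ± 0.807 (SD, n = 2) in rats and 12.8% in the gorilla, where the 95% Wilson interval was 12.76 to 12.79%.

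Rats were compared with dogs by a two-sided exact permutation test on animals, which has 15 splits and cannot give a p below 0.133. The mean level differed by 0.0119 between rats and dogs, less than the SD of the rats, with an exact p of 0.4. The shares of intermediate and of highly methylated CpGs each gave the smallest exact p, 0.133, at rat minus dog differences of 8.05 and -5.82 percentage points, and the share under 0.2 gave an exact p of 0.267. With limits of 0.1 and 0.9 these differences were 5.16 and -2.32 points, and the high share no longer separated the species, at 46.6% in R2 against 45.5% in LAB0026, with PWD0093 lower still. Adjusted by the Benjamini-Hochberg method over the 9 measures compared between rats and dogs, the smallest exact p was 0.2. No difference between these species therefore passed a threshold of 0.05, and species and depth went together, since both rats were covered less than any dog. With reads thinned to a mean of 7.33 in every animal, an alternative chosen after seeing the data, the levels differed by 0.000178.

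The second comparison described hypomethylated regions, the stretches of adjacent CpGs that the model placed in its hypomethylated state. Their number was 105140 ± 1050 (SD, n = 2) in rats, 87025 ± 11016 (SD, n = 4) in dogs and 98900 in the gorilla. They covered 4.92% ± 0.169 (SD, n = 2) in rats, 4.84% ± 0.578 (SD, n = 4) in dogs and 4.96% in the gorilla, as shares of the autosomes at the depths sequenced. With reads thinned to a mean of 7.33 in every animal the shares were 4.80 and 4.96% in the rats, 3.30 to 4.90% in the dogs and 4.76% in the gorilla. A mean level under 0.2 was found in 58.5% of the regions in the gorilla, 50.7 and 52.7% in the rats and 40.4 to 49.0% in the dogs. The regions fell into a class that held a CpG-dense cluster and a class that did not. Regions with a cluster had median lengths of 1887 bp in the gorilla, 1947 to 1986 bp in the rats and 1954.5 to 2041 bp in the dogs, at median levels from 0.0330 to 0.0635. Regions without a cluster were shorter and less fully unmethylated. Their median lengths were 714 bp in the gorilla, 883 and 912 bp in the rats and 462 to 589 bp in the dogs, at median levels from 0.2 in the gorilla to 0.361 in DOB0024.

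Region number, at an exact p of 0.133, was higher in both rats than in any dog. The same held for the length covered, 135 Mb ± 4.63 (SD, n = 2) in rats against 107 Mb ± 12.7 (SD, n = 4) in dogs, and for median region length, 1037.5 bp ± 20.5 (SD, n = 2) against 789.75 bp ± 28.7 (SD, n = 4), each at an exact permutation p of 0.133. The share of the autosomes did not separate the species at the depths sequenced (exact p = 0.933), and the rat minus dog difference was 0.0830 percentage points there and 0.986 with thinned reads. The dog spread in number came largely from DOB0027, with 101295 regions against 76688 to 89846 in the other dogs, and without DOB0027 the rats exceeded the dogs by 22872 regions rather than 18115. With thinned reads the excess was 38349 regions, and the difference in covered length was 48.3 Mb rather than 28.6 Mb, or 13.5 Mb for regions under 0.2. With regions split at gaps over 500 bp, DOB0027 had 110286 regions, more than R1 with 109029 and R2 with 107142, so the separation in number depended on that limit. The length difference changed with depth and with how a region was defined. It was 139.5 bp with thinned reads, 90.8 bp with at least 10 CpGs per region and 31.3 bp with 11-CpG means. Under the last 2 settings DOB0024, at 1330 and 1140 bp, was above R2, at 1328 and 1055 bp. With 11-CpG means DOB0024 was also above R1, at 1081 bp. Among regions with a mean level under 0.2, a filter chosen after seeing the data, the rat mean minus the dog mean was -162 bp.

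**Figure D1:**
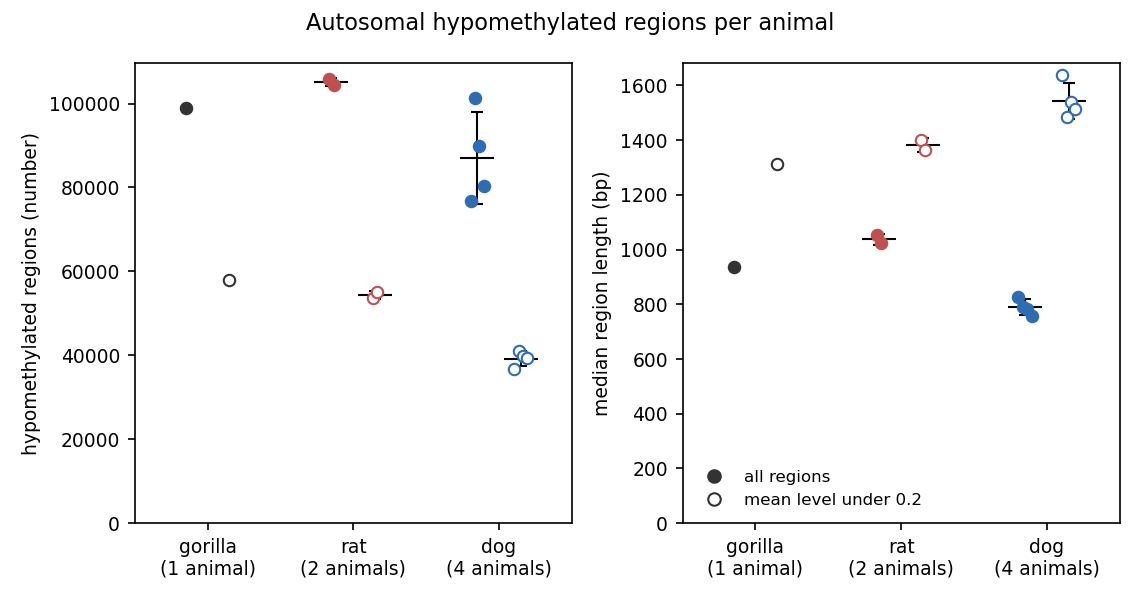
Number (left, regions per animal) and median length (right, bp) of autosomal hypomethylated regions in sperm of each animal. Each point is 1 animal, filled for all regions and open for regions with a mean level under 0.2; horizontal lines are group means and bars are SD over 2 rats or 4 dogs. All regions were fewer and shorter in dogs than in rats, while dog regions under 0.2 were fewer and longer.

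The longest regions, merged over the animals of a species and overlapping a region in each, were far longer in dogs than in rats or the gorilla. Merging joined 4 dogs, 2 rats or 1 gorilla, so these lengths are not on equal terms. Of the longest dog region, 75.9% was called in PWD0093 and 98.8 to 99.6% in the other dogs. Autosomal regions of 10 kb or more in single animals numbered 316 in the gorilla, 91 and 128 in the rats and 154 to 190 in the dogs. In the dog genome (canFam3), 3 of the 5 longest lay on chromosome 26 and the other two on chromosome 8. The longest, chromosome 26 from 25745427 to 26115886, spanned 370 kb with 3320 CpGs and had levels of 0.219 in DOB0024, 0.126 in DOB0027, 0.282 in LAB0026 and 0.508 in PWD0093. Its coverage was 0.965 to 1.16 times the autosomal median of each dog. The region at chromosome 26 from 26743323 to 26959795 spanned 216 kb at levels from 0.126 to 0.443, and that from 26314972 to 26480561 spanned 166 kb at levels from 0.0998 to 0.277. On chromosome 8, the region from 73609306 to 73779191 spanned 170 kb at levels from 0.0803 to 0.148, and that from 72958141 to 73083401 spanned 125 kb at levels from 0.287 to 0.467. Coverage in the former was 1.45 to 3.21 times the autosomal median.

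In the rat genome (rn5), the 5 longest shared regions were 22.1 to 34.1 kb long. They lay on chromosome 14 from 48305576 to 48339714, chromosome 12 from 5468420 to 5502500, chromosome 1 from 186406184 to 186435472, chromosome 18 from 38067685 to 38092397 and chromosome 1 from 187482385 to 187504450. All but the region from 186406184 on chromosome 1 had 3.89 to 22.3 times the autosomal median coverage. That region had levels of 0.424 in R1 and 0.493 in R2 at 0.956 and 1.49 times the median coverage. In the gorilla, whose genome build is not given in the sources used here, the 5 longest regions were 29.5 to 37.5 kb long. Their positions were chromosome 6 from 60530986 to 60568502, X from 59546950 to 59581289, chromosome 8 from 16280454 to 16314104, chromosome 9 from 49049949 to 49082248 and chromosome 10 from 19808557 to 19838024. Their coverage was 1.76 to 10.5 times the autosomal median.

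CpG-dense clusters, used in place of annotated CpG islands, were mostly unmethylated in rat and gorilla sperm and mostly methylated in dog sperm. A mean level under 0.2 was found in 73.7% ± 0.0885 (SD, n = 2) of clusters in rats, 57.3% in the gorilla (95% Wilson interval 56.8 to 57.7%, 44741 clusters) and 38.4% ± 0.313 (SD, n = 4) in dogs. Clusters with a level over 0.8 made up 52.8 to 56.5% in the dogs, 15.04 and 16.1% in the rats and 18.5% in the gorilla. The number of unmethylated clusters was less unequal than their share. It was 25870 to 26778 in the dogs, 25621 in the gorilla and 18000 and 18173 in the rats. The dog sites formed 69907 clusters, the gorilla sites 47471 and the rat sites 28153. Methylated dog clusters were shorter, with median lengths of 898 to 901 bp and a median of 46 CpGs, than unmethylated ones, with median lengths of 1181 to 1198 bp and medians of 86 or 87 CpGs. The share was higher in both rats than in any dog, by 35.3 percentage points, at the smallest exact permutation p of 0.133.

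CpGs in dense surroundings were the least methylated in every animal. From CpGs with 0 to 2 neighbours within 250 bp to those with 41 or more, the mean level fell by 0.779 in the gorilla, by 0.840 ± 0.00705 (SD, n = 2) in rats and by 0.731 ± 0.0357 (SD, n = 4) in dogs. At 11 to 20 neighbours the level was 0.782 to 0.803 in the dogs against 0.637 and 0.657 in the rats and 0.614 in the gorilla. At 21 to 40 neighbours the level was 0.246 in the gorilla, 0.156 and 0.183 in the rats and 0.595 to 0.655 in the dogs. At the highest density the level was 0.0365 in the gorilla, 0.00988 and 0.0154 in the rats and 0.0798 to 0.163 in the dogs, with DOB0027 the lowest dog. At a minimum of 10 reads the order at the highest density changed, with DOB0027 at 0.0278 below R2 at 0.0664 and the gorilla at 0.0792, and LAB0026 at 0.0888. No test was planned for this measure. In DOB0027 mean coverage was 21.5 reads in the sparsest class and 5.94 in the densest, where 38.7% of CpGs were measured, against 75.4 to 91.0% in the other dogs. The densest class was measured as thinly outside the dogs, at 43.5% of CpGs in R1, 26.5% in R2 and 35.4% in the gorilla.

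**Figure D2:**
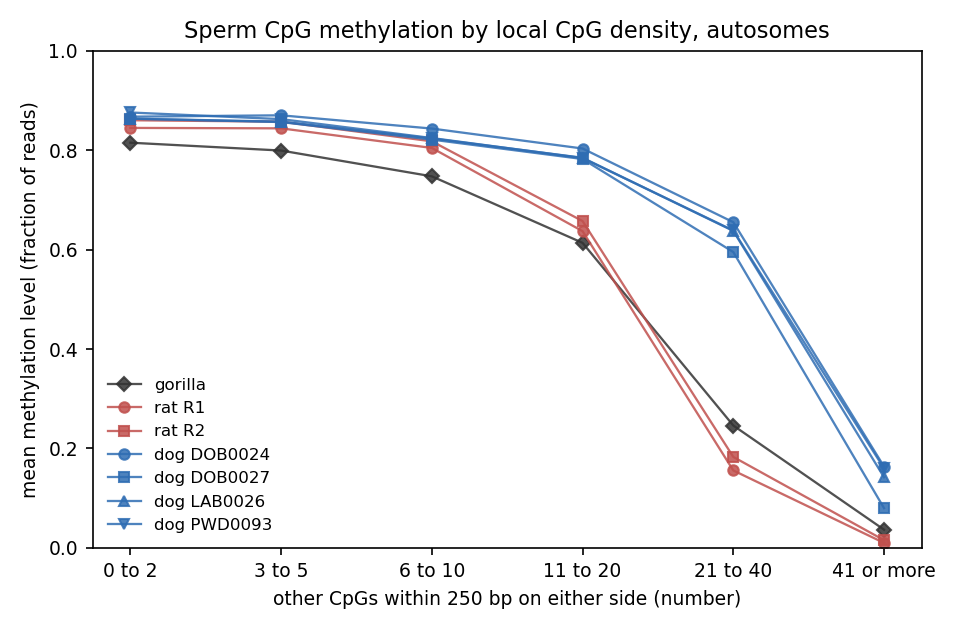
Mean methylation level (fraction of reads, vertical axis) against the number of other CpGs within 250 bp on either side (horizontal axis), for autosomal CpGs with at least 5 reads. Each line is 1 animal, coloured by species. At 21 to 40 neighbours the 4 dogs lie between 0.595 and 0.655, above the rats and the gorilla.

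The X chromosome, present as a single copy in males, was compared with the autosomes of the same animal. It was less methylated than the autosomes in every dog, by a mean level difference of -0.0288 ± 0.00268 (SD, n = 4). In both rats it was lower by a small margin, with a mean difference of -0.00844 ± 0.00542 (SD, n = 2), and in the gorilla it was higher by 0.0286. No test was planned for this measure. Median coverage of X was 3 reads in each rat, 6 in the gorilla and 7 to 12 in the dogs. With a minimum of 3 reads in place of 5, the rat difference was -0.000852 and R2 alone gave 0.00336, so the sign in rats depended on the coverage minimum.

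Animals of a species shared most of their hypomethylated regions. The rats shared 84.9% of regions by any overlap, with a Jaccard index of 69.6% of bases, and the 6 dog pairs shared 78.2% on average (75.2 to 80.8%). After regions were shifted by 1 Mb these shares were 11.5% and 10.1%. Of the regions with a mean level under 0.2 in an animal, a group chosen after seeing the data, 95.6% in the rats and 95.9% in the dog pairs overlapped a region of the other animal. The Dobermans shared 76.9% of their regions, and the other 5 dog pairs shared 78.5% on average, from 75.2 to 80.8%. At this measure the Doberman pair fell inside the range of pairs from different breeds, and no test was made because pairs that share a dog are not independent. The Doberman pair minus the mean of the other pairs was -1.62 percentage points, -4.09 with reads thinned to the same mean coverage and 0.364 for regions under 0.2, where the Doberman pair was the highest of the 6 at 96.2%. Across clusters, which are not independent replicates, levels of the rats correlated at r = 0.990 and those of the dog pairs at r from 0.98 to 0.994.

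The next comparison asked where the sperm methylomes of the 2 rats differed. Of 87926 regions hypomethylated in either rat, 3158 differed by at least 0.2 at an adjusted p under 0.05, with 1892 higher in R2 and 1266 lower. With reads scaled down for the spread of CpGs within regions, an alternative chosen after seeing the data, 180 passed. The regions had been called from the same reads, so read sampling that led to a call in only 1 rat also favoured a difference there. In 1-kb tiles, which do not rest on region calls, 2143 of 1315194 passed, or 0.163% against 3.59% of the regions. Tiles span the genome rather than hypomethylated regions alone. These shares thus cannot show how many of the 3158 follow from that choice of regions. The 3158 regions were short and poor in CpGs, with a median of 608 bp and 9 CpGs, against 1314 bp and 17 CpGs in the regions that did not pass. The test called 1.04% of regions with a CpG-dense cluster, against 4.28% of those without one. At 22 regions the rats had opposite states, with 14 over 0.8 in R1 and under 0.2 in R2 and 8 the other way round.

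The largest difference lay on rn5 chromosome 6 from 100546192 to 100547849, where 17 CpGs had a level of 0.906 in R1 and 0.0340 in R2 (Fisher exact adjusted p = 4.39e-52, 127 and 147 reads). On chromosome 11 from 75595123 to 75596039 the levels were 0.910 in R1 and 0.0403 in R2. On chromosome 13 from 83606618 to 83607035 they were 0.924 and 0.0984, and on chromosome 16 from 5816464 to 5817337 they were 0.929 and 0.110. Rat R2 was also the lower animal on chromosome 2 from 75704020 to 75704655 (0.879 in R1, 0.0618 in R2), where it had 453 reads against 149. The same direction held on chromosome 15 from 65105743 to 65106460 (0.932, 0.138), chromosome 3 from 63187623 to 63189286 (0.861, 0.0777) and chromosome 18 from 83457289 to 83458305 (0.852, 0.1). On chromosome 12 R2 was the higher animal at 2 regions, from 28997274 to 28997517 (0.156 in R1, 0.948 in R2) and from 28881150 to 28882322 (0.0929, 0.853). In the regions on chromosomes 15 and 18 and the former on chromosome 12, 5 or 6 of the 6 CpGs carried the mark CpGx, which the submitters gave to 2.09% of listed CpGs in R1 and 2.07% in R2. What that mark stands for is not given in the sources used here, so the values of these 3 regions are open to doubt.

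**Figure D3:**
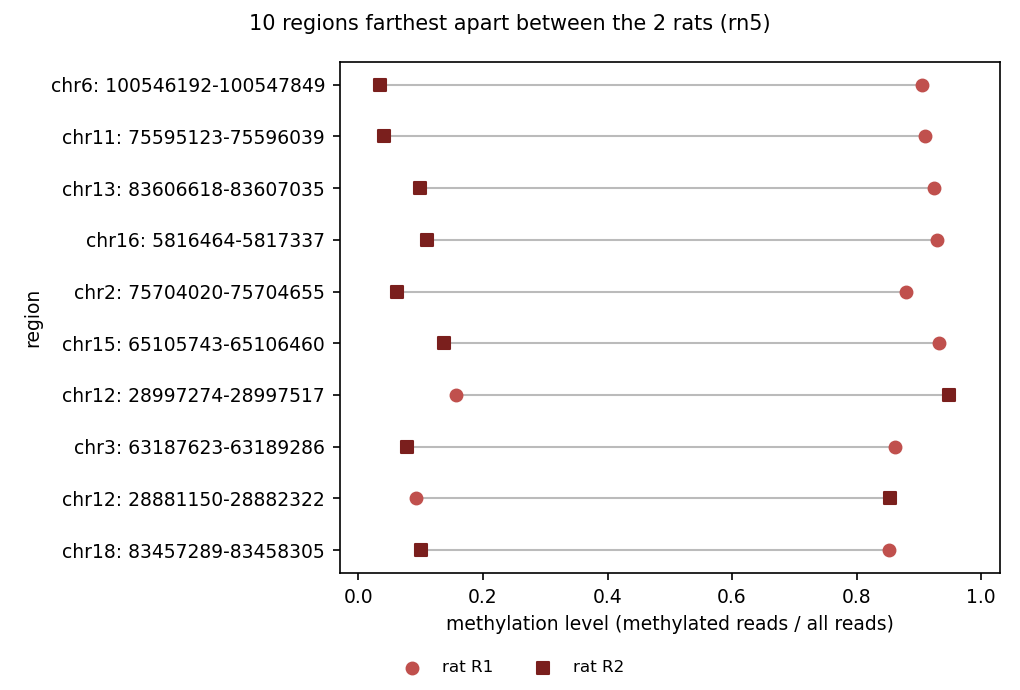
Methylation level (methylated reads over all reads, horizontal axis) of rats R1 and R2 in the 10 regions with the largest difference among those that passed the Fisher exact test, listed by rn5 position (vertical axis). Each symbol is 1 rat and grey lines join the pair. R2 is lower in 8 of the 10 regions.

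The test was a two-sided Fisher exact test on summed reads with Benjamini-Hochberg adjustment, and it compared 1 animal with 1 animal, so its p-values cover reads and not variation among rats. Levels of CpGs within regions varied 3.04 (R1) and 3.03 (R2) times as much as binomial counting allows. That spread can include level differences between CpGs that both rats share. It is thus not a measure of dependence among reads or of variation among rats. All 10 named regions were among the 180 that passed with reads scaled down by the mean of the factors of R1 and R2.

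The last comparison asked whether the Dobermans differed from the Labrador and the Portuguese water dog, breed being the only label that groups the dogs. The planned test called 0 of 104321 regions. The regions with the widest separation nonetheless had nearly opposite states in Dobermans and in the other two dogs. On canFam3 chromosome 16 from 45194254 to 45194572 the level was 0.895 in DOB0024 and 0.95 in DOB0027, against 0.0139 in LAB0026 and 0 in PWD0093 (edgeR adjusted p = 0.627), whose 83 reads allow a level of up to 0.0361. On chromosome 25 from 21984813 to 21986462 it was 0 in both Dobermans, 0.776 in LAB0026 and 0.890 in PWD0093 (edgeR adjusted p = 0.627), and the 78 and 117 Doberman reads allow levels of up to 0.0385 and 0.0256. These limits take reads summed over the 5 CpGs of each region as independent. A fragment can count at several CpGs, so the limits may be too low. At 114 regions both Dobermans stood over 0.5 above or below both other dogs, 38 above and 76 below, a count chosen after seeing the data. The other ways to split the 4 dogs into pairs gave 11 and 25 such regions.

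The planned edgeR quasi-likelihood test, with an adjusted p under 0.05 and a difference of at least 0.2, had 2606 regions at an unadjusted p under 0.05 and a smallest adjusted p of 0.486. The planned limma test on logit levels called 0, with 3284 at an unadjusted p under 0.05, but on simulated data it recovered 0 of 200 changes, so its count carries no information. In a limma test with trend on arcsine square root levels, chosen after seeing the data, 148 regions passed, 53 higher and 95 lower in Dobermans, and 26 and 0 passed in the other splits. At an unadjusted p under 0.05 the breed split had 4201 regions by this test, fewer than the 19492 of DOB0024 and PWD0093 against the others, a split with 21616 by edgeR, which called 0 there. DOB0024 and PWD0093 were also the dogs with the highest coverage. On simulated data the arcsine test made 22 false calls, so its count is not free of error. By edgeR, 29.5% of simulated regions shifted by 0.5 were recovered. Without LAB0026 the edgeR test called 43 regions and without PWD0093 it called 32, which leaves 1 dog against the Dobermans, assumed to vary as they do.

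The 10 regions farthest apart among the 148 were chosen after their values were seen. The Dobermans were the lower group in 8 of them. On canFam3 these lay on chromosome 19 from 3065587 to 3066095, where levels were 0.0656 in DOB0024, 0.0563 in DOB0027, 0.891 in LAB0026 and 0.941 in PWD0093, and on chromosome 15 from 17614378 to 17614764 (group difference -0.834). The chromosome 25 region named before was another (-0.833). Further ones were chromosome 33 from 25288065 to 25288687 (-0.820), chromosome 11 from 50287533 to 50287906 (-0.811) and chromosome 15 from 35467630 to 35468257 (-0.808). The last of these lay on chromosome 27 from 5370859 to 5371426, where 15 CpGs differed by -0.791, and on chromosome 8 from 4321720 to 4322089, where 6 CpGs did (-0.791). The Dobermans were the higher group on chromosome 16, as given before, and on chromosome 10 from 56556686 to 56557490 (0.796). None of these 10 passed the edgeR test after adjustment, with adjusted p from 0.613 to 0.858.

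**Figure D4:**
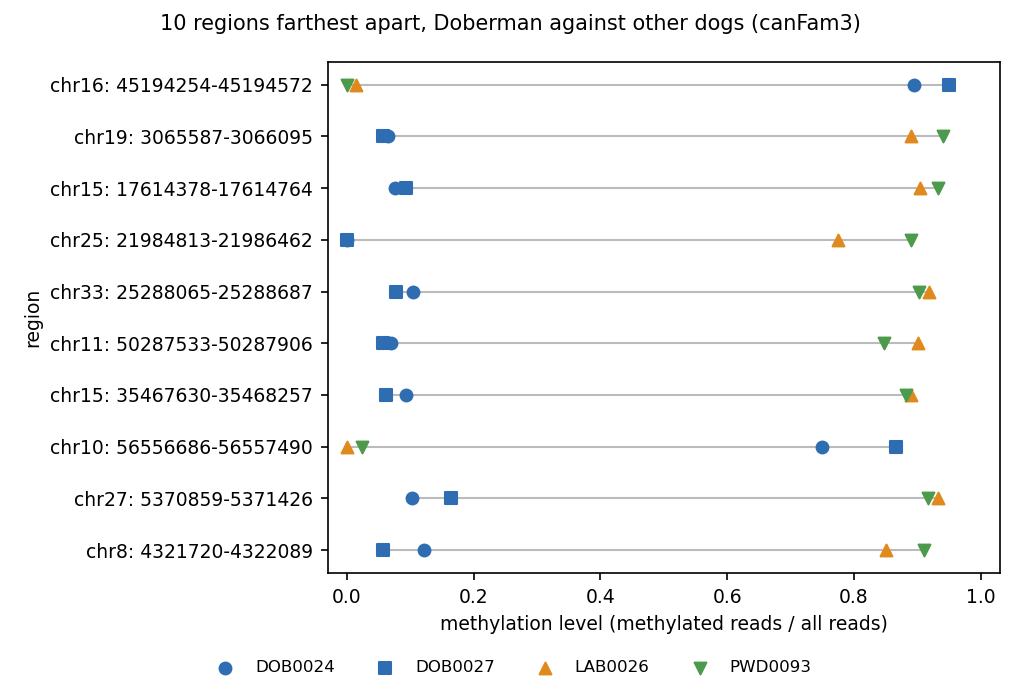
Methylation level (methylated reads over all reads, horizontal axis) of each dog in the 10 regions with the largest difference between Dobermans and the other two dogs among the 148 from limma on arcsine levels, listed by canFam3 position (vertical axis). Each symbol is 1 dog, blue for Dobermans. The Dobermans are lower in 8 of the 10 regions; the regions were chosen after their values were seen.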

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

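The count of regions that set the Dobermans apart by over 0.5, the other splits, the test of 1 CpG per region, the test of DOB0027 at the same mean coverage and all tests on the mitochondrial genome were chosen after the result was seen; the remaining tests were fixed before their values were known.

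At 114 regions both Dobermans stood over 0.5 apart from the Labrador and the Portuguese water dog, a difference that may follow breed or relatedness. Copy number or mapping differences could change coverage, and scaled coverage was over 2 times apart in 5.26% of the regions. Only CpGs with at least 5 reads in every dog were used, so sites lost in a dog were left out beforehand. Coverage changes of up to 2 times would not count either, so this test cannot set these causes aside. A sequence variant that changes reads at 1 CpG alone is argued against. In 0% of the regions did 1 CpG hold enough reads to move both dogs of a side by over 0.5. The minimum of 5 covered CpGs per region nearly fixed that outcome. Variants at several single CpGs cannot be told apart. The choice of regions nearly fixes the test in which 97.4% kept the difference at the median CpG. Of the 3 splits of the 4 dogs, 1 gave as many regions, the real one, and the highest of the other splits gave 25, and 3 splits are too few to reach a share under 0.05. Copy number or mapping differences, variants at several CpGs or outside them, kinship and chance thus stay open. Breed itself was not tested apart from them.

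DOB0027 had 101295 hypomethylated regions, 1.23 times the mean of the other dogs, and 1.06 times among regions with a mean level under 0.2. Lower depth would remove the excess at the same depth, but with reads thinned to the same mean coverage the ratio was 1.46. Loss of coverage at dense CpGs would remove it at equal coverage in every density class, where it was 1.40, and separate region models would remove it under 1 model at that coverage, where it was 1.32. These values argue against depth and separate models as the whole cause, although the 1 model was that fitted to DOB0024. Loss of coverage at dense CpGs cannot be set aside, since only mean coverage per density class was made equal. At that coverage LAB0026 had 84878 regions, against 65201 in DOB0024 and 66623 in PWD0093. Of the densest CpGs, 38.7% had been measured in DOB0027, 75.4% in LAB0026, 89.0% in DOB0024 and 91.0% in PWD0093. Thinning cannot restore fragments lost before sequencing, so a library bias of another kind stays open. No biological explanation was tested, since the other Doberman had the fewest regions, 76688, and no label sets DOB0027 apart.

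On the mitochondrial genome, which the comparisons did not use, 40.2% of reads over CpGs were methylated in LAB0026, against 8.48% in DOB0024, 5.66% in DOB0027 and 15.1% in PWD0093. Poor bisulfite conversion of the whole libraries would raise nuclear levels too. The median level of hypomethylated nuclear clusters in LAB0026 was 0.889 times the highest of the other dogs. Clusters raised over 0.2 would drop out of that set, which would lower the share of hypomethylated clusters. That share was 38.60% in LAB0026, against 37.93 to 38.57% in the other dogs. Reads from nuclear copies that all the dogs carry would give like methylated depth relative to the autosomes, but that of LAB0026 was 3.02 times the highest of the other dogs. Poor conversion of the mitochondrial DNA alone cannot be told apart, because the values hold 0 cytosines outside CpGs. Nuclear copies carried by LAB0026 alone were not tested either, and no biological explanation was tested.

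Methylated reads on the mitochondrial genome also exceeded the share that 3 reads would make in the other species, at 18.5% in the gorilla, 0.696% in rat R1 and 1.66% in rat R2, where those shares were 0.00930%, 0.0209% and 0.0482%. In the dogs the share that 3 reads would make was 0.0106 to 0.0147%. That limit covers counting error only, and unconverted cytosines alone would pass it: the nuclear level at the densest CpGs was 0.00988 in R1 and 0.0154 in R2, as fractions, close to their mitochondrial shares, while in the gorilla it was 0.0365, far below its share. In R2 the methylated share was 11.1% in the first 2000 bp of the mitochondrial genome and 0 to 1.12% in the other stretches of that length. In R1 it was 2.89% in the first stretch and 0 to 0.945% in the others. The methylated share was thus uneven along the genome in both rats. Its closeness to the nuclear level over the whole genome therefore does not show that unconverted cytosines made it.

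DOB0027 had 25870 hypomethylated clusters. Its gap to the next dog made up 0.868 of the dogs' range and passed the Dixon limit for 4 values. Fewer clusters were measured in DOB0027, 68205 against 69062 to 69435 in the other dogs. For the share of measured clusters the gap made up 0.806 of the range and did not pass. The low count thus cannot be told apart from the smaller number of clusters measured. Of 23 measures tested, the count was the 1 in which a dog passed that limit, and chance alone gives about 1 in 20. X minus autosomes was 0.0286 in the gorilla, -0.0288 on average in dogs and -0.00844 on average in rats, opposite in sign in the gorilla and in every dog and rat at a minimum of 5 reads. At a minimum of 3 reads rat R2 was at 0.00336, with the sign of the gorilla, and the difference between species was not tested. Unplaced gorilla sequences, outside the comparisons, had a mean level of 0.678, and a further set of gorilla sequences under a separate name had 0.712.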

How the results depend on the processing

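Added alternatives, chosen only after the results were seen, were the limit of 0.2 on a region's mean level, scaled rat reads, arcsine levels, tiles with logit levels, CpGs weighted by all listed densities, differences from the median, rat regions without CpGx sites, and thinned reads for levels and clusters. No paired analysis was possible because library and animal numbers only name samples and the species have different genomes. Of 146 alternatives, 125 were read as the same, 6 as reversed and 15 as moved. Rat against dog differences counted as the same whenever their direction held, whatever their size. Other values moved past the SD of replicates or pairs or the counting interval, and counts past 1.5 times. Of the 90 on rats against dogs, 84 kept their direction, but in a test that cannot reach 0.05 this says nothing of stability. The rat minus dog difference was 5.16 points in the intermediate share and -2.32 in the high share with limits of 0.1 and 0.9. In covered length, 28.6 Mb, it was 48.3 Mb with thinned reads, 18.4 Mb with 11-CpG means and 13.5 Mb for regions under 0.2. The rat excess in median region length of 247.75 bp became -162 bp for regions under 0.2, where regions of higher level drop out, 139.5 bp with thinned reads, 90.8 bp with at least 10 CpGs and 31.3 bp with 11-CpG means. The difference in the share of the autosomes, 0.0830 points, became -0.074 with at least 10 CpGs per region, -0.155 for regions under 0.2, 0.986 with reads thinned to the same mean coverage and from -0.0781 to 0.336 leaving out each animal. It was -0.0362 without R1, -0.0561 without DOB0024 and -0.0781 without PWD0093; the cause was not tested. With reads thinned so, which leaves coverage by density unequal, the rat excess in region number was 38349. The level difference ranged from 0.000178 (thinned) to 0.0249 (without CpGx sites, planned) and was 0.000918 without R2 and 0.0230 without R1.

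The rat overlap was 79.3% when at least 50% of a region had to be covered, a stricter rule by construction, and 95.6% for regions under 0.2. The Doberman pair minus other pairs was -4.09 points with thinned reads and turned from -1.62 to 0.364 for regions under 0.2. The fall with density was 0.786 within 500 bp and 0.740 at 10 reads in the gorilla, and 0.810 at 10 reads in rats, against 0.763 in dogs, which reverses the order of gorilla and dogs. X minus autosomes in rats was -0.000852 at 3 reads. The cause of these shifts was not tested. Rat regions numbered 1447 at a difference of 0.3, a subset by construction, and 180 with scaled reads, which counts fewer reads. For the dogs, limma on arcsine levels gave 148 regions by breed and 26 for DOB0024 with LAB0026 against the others. Leaving out each dog, edgeR gave 0 to 43: 43 without LAB0026, 32 without PWD0093, and 0 without either Doberman (6984 without DOB0024 and 3051 without DOB0027 at an unadjusted p under 0.05). Splits of the dogs other than by breed gave 0 by edgeR, with 726 and 21616 at an unadjusted p under 0.05. The latter split, DOB0024 with PWD0093, sets the more deeply covered dogs against the less covered ones. Mean coverage of listed CpGs was 23.3 and 27.6 reads in that pair, against 14.3 in DOB0027 and 18.4 in LAB0026. Depth and other differences between these pairs thus cannot be told apart, and the cause was not tested. Tiles gave 0 by edgeR and by limma on logit levels, with 76316 and 75778 at an unadjusted p under 0.05. Promoters of gene lists were not run, with their alternatives on windows, limits, coverage and left-out animals, because no annotation of these builds was used here. Depth limits X in rats, at a median of 3 reads, and the densest CpGs in DOB0027, the rats and the gorilla, of which 26.5 to 43.5% were measured.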

Other observations

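Apart from the planned level at CpGx-marked CpGs, every measure and test in this part was chosen after the data were seen. Methylation rose over a longer distance from unmethylated CpG-dense clusters in gorilla sperm than in the other animals. The mean level came midway between 0 and its level 4 to 5 kb away at 694 bp in the gorilla, 471 and 491 bp in the rats and 322 to 355 bp in the dogs. From 901 to 1000 bp outside a cluster the level was 0.507 in the gorilla, 0.685 and 0.709 in the rats and 0.755 to 0.776 in the dogs. The gorilla exceeded the highest other animal by 203 bp. It did so by 234 bp with reads thinned to the same mean coverage, 288 bp at a minimum of 10 reads, 221 bp for clusters under 0.1 and 181 bp over all covered CpGs. The gorilla value rests on 1 animal and was not tested.

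The same autosome was the least methylated in all animals of a species, in most of them by a small margin. The least methylated autosome was chromosome 19 in the gorilla (0.627, with chromosome 4 next at 0.679). It was chromosome 12 in both rats (0.711 in R1 and 0.737 in R2), with chromosome 20 next at 0.718 and 0.740. In every dog it was chromosome 32 (0.702 to 0.721), with the next autosome at 0.705 in PWD0093, 0.715 in LAB0026, 0.718 in DOB0024 and 0.744 in DOB0027. Among regions of dogs in which 1 animal stood over 0.5 from the other 3, PWD0093 had 223, LAB0026 206, DOB0027 96 and DOB0024 50. The 114 regions that set the Dobermans apart were short, with a median of 6 CpGs and 570.5 bp, and 8.77% held a CpG-dense cluster, against 30.5% of all regions tested.

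Tiles of 1 kb with at least 10 times the median read number had lower levels over their pooled reads than the rest of the genome in every animal, though most of them were not under 0.2. In the dogs 984 to 1402 such tiles held 4.09 to 5.07% of reads at levels from 0.205 to 0.251, against 0.735 to 0.789 elsewhere. All dogs shared 787 of the 1628 found in any dog, and both rats shared 914 of 1125. In the rats these tiles had levels of 0.378 and 0.403, and in the gorilla 372 tiles had a level of 0.374. A level under 0.2 was found in 220 of 1020 such tiles in DOB0024, 457 of 1402 in DOB0027, 343 of 984 in LAB0026, 430 of 1065 in PWD0093, 69 of 960 in R1, 62 of 1079 in R2 and 53 of 372 in the gorilla. Rat CpGs marked CpGx had a mean level of 0.102 in both rats.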
